A study of Mus musculus with 6 samples.

How the data were processed

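The series holds 6 single-cell RNA libraries of mouse cells, each its own group of 1 library. Per the labels' protocols, cells were dissociated, sorted by flow cytometry and loaded for 3' capture with the 10x Genomics version 2 chemistry. The sorted population and its gate are not given in the sources used here. Each library has a matrix of UMI counts per gene and cell barcode as deposited, which Cell Ranger 6.0.1 made against mm10, per the submitters' processing notes. The deposited counts were whole numbers and had not been normalized. They cover 32285 genes, the same in all libraries, and 78 genes that share a symbol were told apart by identifier. All 6 matrices were used. The P6 and P10 libraries carry barcodes of another barcode list than the P9 libraries, although the labels name 1 chemistry, so the P9 pair was compared only within itself in the main results. Gene coordinates were taken from the GENCODE vM21 annotation of GRCm38, in which 32158 of the identifiers matched.

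Groups were taken from the labels for genotype, treatment and harvest day. The day of the P9 libraries came from their description label. Total counts ranged from 10807651 to 40197132 UMIs per library, so a gene at 20 CPM in endothelial cells rested on well over 30 UMIs in every library, and shares of cells rested on 740 to 3506 endothelial cells. Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept. This left out 10.5% (WT P6), 21.6% (KO P6), 6.41% (WT P10), 11.3% (KO P10), 28.3% (vehicle) and 22.8% (rapamycin) of barcodes. Doublet scores were computed per library with Scrublet in scanpy 1.11.5. Its automatic threshold marked between 0 and 1 cells per library and was judged not to have worked. After seeing this, the highest scores were removed at a rate of 0.8% of barcodes per 1000 barcodes.

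Counts were scaled per cell and log-transformed, 2000 variable genes and 30 principal components were taken, and cells were clustered with 15 neighbours and the Leiden method (leidenalg 0.10.2) at resolution 1.0. Clusters were named from 27 marker lists fixed before the data were examined, using markers among the top 10 genes by fold and their level. Endothelial markers included Pecam1, Cldn5, Cdh5, Flt1, Kdr, Tek, Tie1, Esam and Egfl7. No cluster of pericytes alone was found. A cluster with endothelial genes but more markers of another class was called mixed and left out of the endothelial class, a choice made after seeing the clusters. UMIs were then summed over the endothelial cells of each library, and CPM is the sum per 1000000 endothelial UMIs. Different clusters hold most endothelial cells in different libraries, and clusters 0, 1, 7, 13 and 16 lie almost wholly in the P9 libraries, so cluster sizes were not compared between groups as results, and the clusters that hold most cells are only named.

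Sums carry exact Poisson intervals and shares exact Clopper-Pearson intervals at 95%, which cover counting error only. Log2 ratios use a prior count of 2. For a library at 0, a floor of 3 counts per library was used. Mitotic cells had UMIs of at least 3 of 12 markers after thinning to 2000 UMIs. With 1 library per group no p-value was computed within a pair. A genotype test was run with edgeR 4.0.16 (R 4.3.3), using TMM scaling, filterByExpr, a quasi-likelihood fit with age and genotype as terms, and Benjamini-Hochberg adjustment at 0.05. It used 4 libraries with 1 residual degree of freedom, and its common dispersion was 0.0164. The labels do not say that libraries came from separate animals, so p-values measure only the spread between these libraries. A genotype effect that differs between the ages enters that spread, so a gene apart mainly at 1 age can fail to pass. The procedure was tested on simulated data for this genotype comparison, with 200 genes changed at each fold. It recovered 14% of genes changed 1.5-fold (12359 genes, 4 false calls), 68% of those changed 2-fold (12339 genes, 6 false calls) and 94% of those changed 4-fold (12334 genes, 7 false calls). The simulated counts took their dispersion from the trend of this same fit and had the same fold at both ages. Genes whose genotype ratio differs between the ages were not simulated, so these rates need not hold for the real libraries.

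Before the data were examined, 28 gene lists and the rule for named genes were fixed. The rule takes genes with at least 20 CPM and 30 UMIs in the higher library of each pair concerned. For genotype it takes the 10 higher and 10 lower genes with the same sign at both ages, ranked by the smaller ratio. It takes 5 each way for P6, P10 and age in WT, and 10 each way for rapamycin. Mitochondrial, ribosomal protein, haemoglobin, Xist, Y-linked and unnamed gene models were left out of the ranking, as were genes whose endothelial CPM lay under a 0.1 share of their highest level in a non-endothelial cluster, where free RNA could supply it. Members of the fixed lists may also be named. A list's median was set among 10000 random lists of the same size matched on mean expression in 20 bins. Later additions, made after seeing values, were a list of p53 target genes and a list of genes that escape X inactivation.

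Alternatives tried were other cell filters (200 genes with 20% mitochondrial UMIs, or 1000 genes with 5%), doublets kept, resolution 2.0, a rule per cell (at least 3 of 6 endothelial markers), mixed clusters counted as endothelial, cells without mitosis, other scalings, prior counts and minima, and cells weighted equally. For the genotype test they were DESeq2 1.42.0, limma 3.58.1 with voom, DESeq2 size factors, no count filter, no age term, all 6 libraries and each library left out. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.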

Results

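Single-cell transcriptomes of sorted cells were profiled from young mice in which the cerebral cavernous malformation gene Pdcd10 (also called Ccm3) was floxed and Cre was driven by the Mfsd2a locus after tamoxifen. Mfsd2a encodes a lipid transporter of the blood-brain barrier endothelium, and loss of Pdcd10 in endothelium causes clustered, leaky brain vessels. The 6 libraries formed 6 groups of 1 library each. They were WT (Cre without the floxed allele) and KO (Cre with the floxed allele) given tamoxifen at postnatal day (P) 1 and harvested at P6 or P10, and KO mice harvested at P9 after vehicle or rapamycin, an inhibitor of the kinase complex mTORC1. The labels do not give the tamoxifen day of the P9 mice. No library was repeated, so a difference within a pair has no replicate check and no p-value is given for it.

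The files held 18568 cell barcodes and 132319693 unique molecular identifiers (UMIs), each standing for 1 captured transcript. Total UMIs were 12080868 in WT at P6, 10807651 in KO at P6, 21271326 in WT at P10 and 24216567 in KO at P10. The P9 totals were 40197132 with vehicle and 23746149 with rapamycin. After filtering, 14709 cells remained in 23 clusters, of which 16 were endothelial-like and held 12499 cells. Endothelial cells numbered 1097 (WT P6), 740 (KO P6), 2949 (WT P10), 2738 (KO P10), 3506 (vehicle) and 1469 (rapamycin), with summed endothelial UMIs from 8185677 in KO at P6 to 31896117 with vehicle. Median UMIs per endothelial cell ranged from 4511 in WT at P10 to 10927 with rapamycin. Expression below is in UMIs per 1000000 endothelial UMIs (CPM), and all intervals are exact 95% intervals that cover counting error only.

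The labels name retina as the tissue, whereas the series title and design name brain. Summed over all kept cells, 13 retina markers reached 4.41 to 8.93 CPM, and the photoreceptor gene Rcvrn had 0 UMIs in all 6 libraries. Markers of cerebellar granule neurons, which are found in brain, reached 135 CPM in WT and 153 CPM in KO at P6, and 24.8 to 76.9 CPM in the other libraries. At P10 the granule neuron cluster held 0 cells, and Neurod1 had 0 UMIs in WT and 4 in KO. Zic1 alone gave 339 of 867 marker UMIs in WT and 196 of 560 in KO at P10. The P10 sums are therefore not read as granule neurons, and whether the list separates brain from retina was not tested. Choroid plexus markers reached 3188 CPM in the rapamycin library and at most 161 CPM in the others, with Ttr alone giving 68510 of these 70731 rapamycin UMIs. In the others, Enpp2 UMIs of endothelial cells made up most of the sum, such as 1493 of 1879 in WT at P6 and 1444 of 1705 with vehicle. Those sums are therefore not read as choroid plexus RNA.

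The targeted gene was lower in the KO libraries. Pdcd10 (ENSMUSG00000027835, mm10 chromosome 3, 75516490 to 75556856, minus strand) measured 102 CPM (interval 95.6 to 109) in WT at P6 and 105 CPM (99.8 to 110) in WT at P10. In KO it measured 56.8 CPM (51.8 to 62.2) at P6 and 57.9 CPM (54.7 to 61.3) at P10. In the P9 KO mice it measured 44.1 CPM (41.9 to 46.5) with vehicle and 79.9 CPM (76.0 to 83.9) with rapamycin. Across the 4 libraries of P6 and P10, Pdcd10 fell by 0.88 on the log2 scale (SE 0.10, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0137). The labels do not say which exons were floxed, and a 3' tag outside the deleted part would still be counted, so the remaining level does not measure the share of recombined cells.

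**Figure D1:**
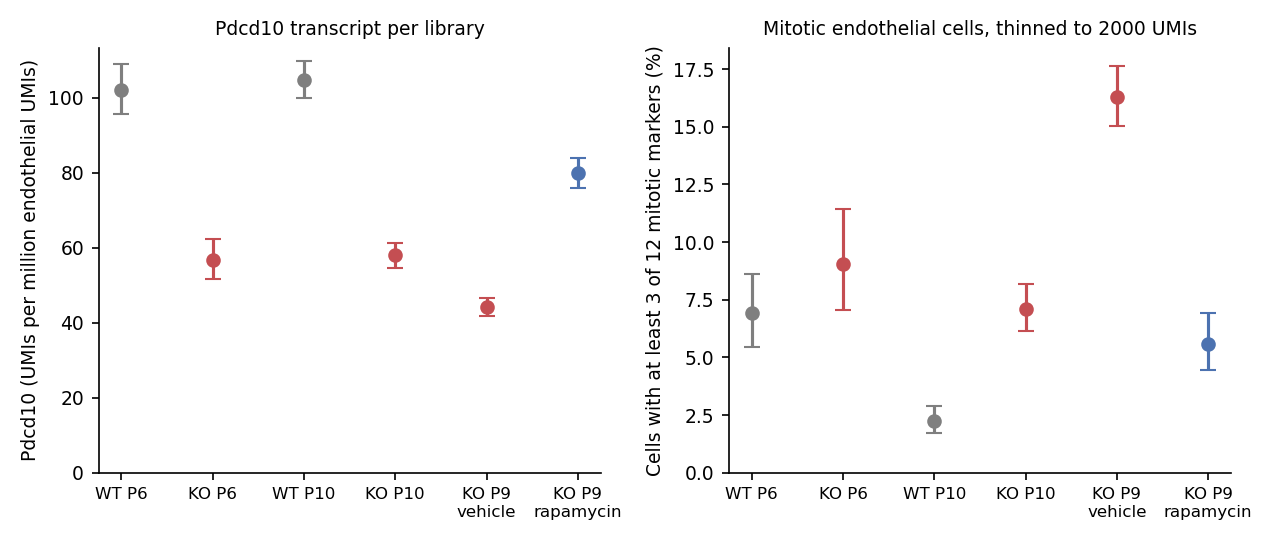
Pdcd10 level in endothelial cells (CPM, left) and share of endothelial cells with UMIs of at least 3 of 12 mitotic markers after thinning to 2000 UMIs per cell (percent, right), 1 library per group with exact 95% counting intervals as bars. Pdcd10 lay at 102 and 105 in the WT libraries and between 44.1 and 79.9 in the KO libraries, and the mitotic share ran from 2.26% in WT at P10 to 16.3% in KO with vehicle.

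Endothelial-like cells made up most of every library. Their share of kept cells was 75.2% (72.9 to 77.4) in WT and 78.7% (76.0 to 81.3) in KO at P6, and 84.5% (83.3 to 85.7) in WT and 91.0% (89.9 to 92.0) in KO at P10. It was 86.0% (84.9 to 87.1) with vehicle and 84.7% (82.9 to 86.3) with rapamycin. Clusters with endothelial genes but more pericyte markers, the contractile cells that wrap capillaries, were kept apart as mixed. They held 18.0% (WT P6), 12.1% (KO P6), 10.98% (WT P10), 5.92% (KO P10), 2.65% (vehicle) and 3.86% (rapamycin) of kept cells. Other mixed clusters held astrocyte, red cell or microglial markers. Cells were sorted by flow cytometry before loading, and the sort sets these shares in part.

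Dividing endothelial cells were more frequent in KO than in WT at P10 and less frequent with rapamycin than with vehicle. After thinning each cell to 2000 UMIs, 2.26% (1.72 to 2.91) of WT and 7.11% (6.13 to 8.19) of KO endothelial cells at P10 had UMIs of at least 3 of 12 mitotic markers, such as Mki67 and Top2a. At P6 the shares were 6.93% (5.47 to 8.63) in WT and 9.07% (7.05 to 11.4) in KO, with overlapping intervals. The share was 16.3% (15.03 to 17.6) with vehicle and 5.59% (4.45 to 6.92) with rapamycin, a ratio of 0.343. With 1 marker instead of 3, the ratio of KO to WT at P10 went from 3.15 to 1.41, and that of rapamycin to vehicle to 0.435. Without thinning the shares were 14.3%, 20.3%, 3.49%, 12.1%, 24.96% and 8.92% in the order WT P6, KO P6, WT P10, KO P10, vehicle and rapamycin. Thinning left out 43, 34, 382, 249, 328 and 55 shallower cells in that order. As a background, with cells of the vehicle library thinned to 500 UMIs, a check added after seeing the data, 1.49% (0.548 to 3.21) of neuron-like cells (median 838 UMIs before thinning) and 18.6% (17.3 to 19.9) of endothelial cells (median 7496) had a UMI of at least 1 marker.

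The genotype comparison asked what differed in endothelial cells with deletion of Pdcd10 early after birth. Several interferon-stimulated genes and the chemokine Ccl5 were far higher in KO at both ages, together with Phlda3 and Gdf15, which are p53 target genes. Genes that were lower include those of the selenium carrier Selenop, the lipid carrier Apoe and the iron carrier transferrin (Trf). Rsad2, an antiviral enzyme (chromosome 12, 26442746 to 26456452), rose from 1.12 CPM in WT to 73.3 CPM in KO at P6 and from 0.746 to 42.0 CPM at P10, a log2 fold change of 5.87 (SE 0.19, adjusted p = 0.000396). Phlda3 rose with a log2 fold change of 4.79 (SE 0.16, adjusted p = 0.000396), from 4.81 to 162 CPM at P6 and from 5.72 to 142 CPM at P10. Ccl5, which draws leukocytes, rose by 6.48 (SE 0.64, adjusted p = 0.00849). WT at P10 had 1 Ccl5 UMI, so its ratio there, 1873, has a counting interval of 336 to 74000. Selenop (chromosome 15, 3268547 to 3280508) fell by 1.95 (SE 0.15, adjusted p = 0.00427), from 4183 to 1044 CPM at P6 and from 3528 to 995 CPM at P10.

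In edgeR's quasi-likelihood test on summed endothelial counts with harvest age as a term, 387 of 12527 genes were higher and 228 lower in KO at an adjusted p of 0.05. The test rests on 4 libraries and 1 residual degree of freedom, with the ages as the only repeats. A genotype effect that differs between the ages enters the residual, so failing to pass is not read as no difference. Besides Rsad2, Ccl5 and Phlda3, the 10 genes named as higher were Ccdc184, the interferon-induced Ifit1 and Oasl2, Gdf15, the leukotriene C4 synthase Ltc4s, the uridine phosphorylase Upp1 and Plvap, a protein of fenestrated and leaky endothelium. Their log2 ratios ran from 2.65 (Plvap) to 5.76 (Rsad2) at P6 and from 2.82 (Oasl2) to 9.41 (Ccl5) at P10. Of the Plvap UMIs in KO, 77.1% at P6 and 86.8% at P10 lay in a single small cluster led by Plvap. Those named as lower included Selenop, Apoe, Trf, Ddc, Scgb3a1, the mitochondrial carrier Slc25a33, the transcription factor Pou2f2, Enpp2 and Hmcn1, with log2 ratios of -1.10 (Hmcn1) to -2.16 (Apoe) at P6 and -1.09 (Enpp2) to -2.47 (Ddc) at P10. Astrocyte markers summed over all kept cells, which include sources of Apoe, measured 182 CPM in WT and 175 CPM in KO at P6, and 287 and 203 CPM at P10. In the non-endothelial cluster where each was highest, Apoe reached 3350 CPM and Ddc 307 CPM. Their highest endothelial levels at P6 and P10 were 721 and 43.1 CPM, both in WT at P10. The mixed pericyte share was also lower in KO at both ages, so free RNA was not excluded for Apoe and Ddc. All genes named here passed the threshold in edgeR, the highest adjusted p being 0.0237 for Ddc. They were picked by large ratios of the same sign at both ages in these libraries, so passing is not independent support. Without the age term edgeR called 2 genes (1084 at an unadjusted p under 0.05), and on all 6 libraries, with harvest day as a number and a rapamycin term added, it called 0 (1044 at an unadjusted p under 0.05). With 3 libraries and no age term it called 3 genes without WT at P6, 7 without KO at P6, 1 without WT at P10 and 111 without KO at P10.

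**Figure D2:**
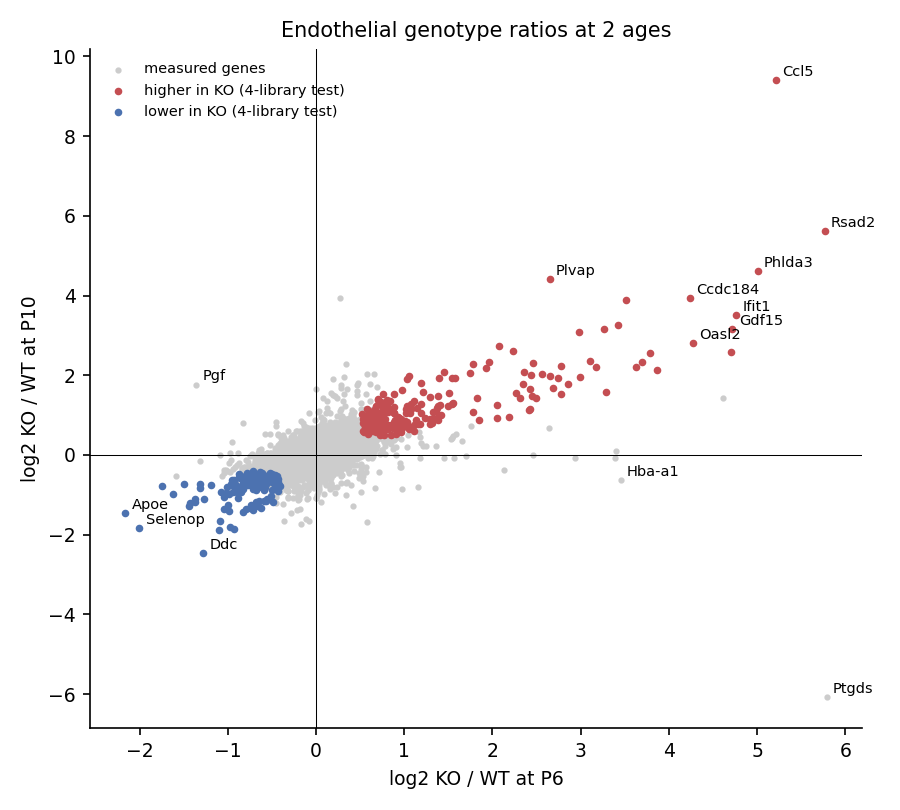
Log2 ratio of KO to WT in endothelial cells at P6 (horizontal axis) and at P10 (vertical axis), 1 point per measured gene, 1 library per group, with named genes labelled. Across 5448 genes the ratios had a Pearson r of 0.673, and Rsad2 lay at 5.76 and 5.62.

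Among the lists fixed beforehand, interferon-stimulated genes had the largest share of calls. Of 20 tested, 15 rose in edgeR and 5 did not pass, and 17 rose when adjusted over the list alone. In this fit 2970 of all 12527 genes had an unadjusted p under 0.05 (edgeR). A short list adjusted alone can therefore pass many members, so such counts, here and below, are not read as enrichment. Isg15, a ubiquitin-like antiviral protein, rose by 2.98 on the log2 scale (SE 0.32, adjusted p = 0.0103), from 29.8 to 390 CPM at P6 and from 21.2 to 107 CPM at P10. B2m, the light chain of MHC class I, rose by 1.39 (SE 0.19, adjusted p = 0.0214), and Irf7 and Ifitm3 rose as well. The list median was 3.02 at P6 and 1.69 at P10, above all 10000 random lists of matched expression at both ages. Outside cluster 4, which is led by interferon genes, summed interferon genes still measured 8506 CPM in KO against 2117 CPM in WT at P6, and 3855 against 2364 CPM at P10. WT at P6 carried Xist UMIs, and KO at P6 carried almost neither Xist nor Y-linked UMIs, so these libraries also differ in sex-linked expression.

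Genes of cell division and of ribosome production leaned upward in KO. Of 20 S phase genes, 5 rose in edgeR (Mcm5, Mcm7, Gins2, Dut and Ccne1) and 15 did not pass, and 15 rose adjusted over the list alone. Mcm5, part of the replicative helicase, rose by 1.01 (SE 0.19, adjusted p = 0.0425). Of 22 genes of G2 and mitosis, only the mitotic kinase Aurka passed as higher, and 18 rose adjusted over the list alone. The list median was 0.46 at P6 (17 measured members) and 1.71 at P10 (12 measured), and such a difference between ages enters the residual. Mki67, a marker of cycling cells, had log2 ratios of -0.20 at P6 and 1.29 at P10 (edgeR adjusted p = 0.411). Of 28 genes of the ribosome biogenesis and nucleotide arm downstream of mTORC1, 5 rose (Dkc1, Umps, Nme1, Eif4ebp1 and Hspd1) and 23 did not pass, and 19 rose adjusted over the list alone. Without mitotic cells the S phase median at P6 turned from 0.47 to -0.07, and that of the ribosome biogenesis arm went to 0.29.

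The amino acid arm downstream of mTORC1 and ATF4 moved both ways. Of 24 genes, Asns, Phgdh, Nupr1 and Gars rose, Slc7a5, Slc3a2 and Slc7a1 fell, and 17 did not pass, with 11 rising and 3 falling when adjusted over the list alone. Phgdh, the first enzyme of serine synthesis, rose by 1.47 (SE 0.18, edgeR adjusted p = 0.0155). The 3 that fell are amino acid transporters of the plasma membrane, and Slc7a5 and Slc3a2 together form the large neutral amino acid transporter of the barrier. In the glycolysis and hypoxia arm 1 of 28 genes rose (Ndrg1), and 11 did adjusted over the list alone. In the sterol and lipid arm 1 of 26 rose, and 3 did adjusted over the list alone.

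Genes of the blood-brain barrier leaned downward. Of 22 tested in edgeR, 6 fell (the junction scaffold Tjp1, the transporters Slc7a5, Slc3a2, Slc16a1 and Slc22a8, and the transcription factor Foxq1) and 16 did not pass, while 14 fell adjusted over the list alone. Slc22a8, an organic anion transporter, fell by 0.97 (SE 0.15, adjusted p = 0.0281). Cldn5, the main tight junction claudin of brain endothelium, had log2 ratios of -0.33 at P6 and 0.04 at P10 (adjusted p = 0.583). Mfsd2a, whose locus drives the Cre, had log2 ratios of -0.37 and -1.67 (adjusted p = 0.102). Of 19 genes of Wnt and barrier signalling, Apcdd1 and Sp5 fell, and 7 fell adjusted over the list alone. Of 10 capillary genes, Slc16a1, Slc7a5, Spock2 and Slc7a1 fell, and 8 fell adjusted over the list alone. Of 11 Notch genes, the ligand Dll4 and the target Hey1 fell, and 4 fell adjusted over the list alone.

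Genes linked to leak, sprouting and leukocyte recruitment rose in part. Of 14 genes of vascular leak and fenestration, Plvap, Esm1, Igfbp3, Cav1 and Cav2 rose, Vwf fell and 8 did not pass, with 8 rising and 1 falling adjusted over the list alone. The rise of Plvap rests mostly on the small Plvap-led cluster. Outside it, Plvap measured 4.49 CPM in WT and 8.93 CPM in KO at P6. At P10 it measured 2.18 and 6.48 CPM, and all 4 values lie under the minimum of 20 CPM. Esm1, a proteoglycan of tip cells, rose by 2.23 (SE 0.18, edgeR adjusted p = 0.00565). Of 12 tip cell genes, Apln, Esm1, Plvap, Kcne3 and Mcam rose and 7 did not pass, and 7 rose adjusted over the list alone. Of 19 genes of leukocyte adhesion and inflammation, the adhesion molecule Vcam1, the chemokines Ccl2 and Cxcl9 and the chemokine receptor Ackr1 rose, and 6 rose adjusted over the list alone. Vcam1 rose by 1.66 (SE 0.17, adjusted p = 0.00907). Klf2, a flow-responsive transcription factor raised in CCM lesions, rose by 0.70 (SE 0.14, adjusted p = 0.0455). Of 16 Klf and CCM-linked genes it alone rose and 15 did not pass, and 2 rose adjusted over the list alone. Klf4, a related factor, and Thbd, a target of both, did not pass, with log2 fold changes of 0.29 (adjusted p = 0.219) and 0.58 (adjusted p = 0.0616). S100a6 and S100a10 rose by 3.72 and 3.32 (edgeR adjusted p = 0.000531 for both). Of 17 genes of endothelial-mesenchymal transition, S100a6 alone rose and 16 did not pass. Of 10 endothelial progenitor genes, Ly6a rose and Kit fell, with 2 rising and 4 falling adjusted over the list alone.

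The pair at P6 asked what differed 5 days after tamoxifen. The 5 genes highest in KO were Ttr, Ifit3b, Ptgds, Rsad2 and Ifit3, and the 5 lowest were Apoe, Selenop, the addressin Madcam1, Rpap3 and the ferritin heavy chain Fth1. Ifit3 measured 1.01 CPM in WT and 67.0 CPM in KO. Ifit3b, with 1 UMI in WT and 196 in KO, had a ratio of 214 (interval 37.9 to 8490), and reads of these near-identical neighbours can be split between them. Ttr, the thyroxine carrier made by choroid plexus, had 0 UMIs in WT and 268 in KO, at least 97.48-fold higher against a floor of 3 counts, with 95.2% of its KO UMIs in the Plvap-led cluster. Only 15 KO cells had a Ttr UMI, and 1 of them held 137. Fth1 measured 11300 CPM in WT and 4018 CPM in KO. Different clusters held the endothelial cells, mainly cluster 4 in KO and clusters 14, 6 and 2 in WT.

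The pair at P10 asked the same question later. Ccl5, Ccl2, Rsad2, Phlda3 and Plvap were highest in KO, and Ptgds, Ddc, Hmcn1, Spock2 and Selenop were lowest. Ccl2, a monocyte chemoattractant, measured 0.746 CPM in WT and 56.1 CPM in KO. Spock2, an extracellular proteoglycan, measured 1090 CPM in WT and 302 CPM in KO. The median log2 ratio of G2 and mitosis genes was 1.71 (0.28 without mitotic cells), and that of blood-brain barrier genes was -0.58, with 10 of 21 measured members at least 1.5-fold lower. Immediate early genes, which respond to tissue dissociation, had a median of -0.28 (percentile 0.1 among random lists), so handling may differ within this pair. Red cell markers measured 16040 CPM in all kept WT cells and 4577 CPM in KO cells. The clusters that held most cells were 2 and 3 in WT and 4 and 3 in KO.

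The P9 pair asked how mTORC1 inhibition changed KO endothelium. With rapamycin, the list medians of cell division genes were lower, as were Ccl5, Ltc4s, Ccdc184 and Rsad2, which had been among the genes highest in KO. The list medians of barrier, capillary and Notch genes were higher. Ccl5 measured 50.5 CPM with vehicle and 2.42 CPM with rapamycin, a log2 ratio of -4.34. Ltc4s went from 171 to 17.3 CPM and Rsad2 from 36.9 to 5.79 CPM. Others named as lower were Hebp1, Serpinb1a, Cd109, Nts and Anxa1, with log2 ratios from -4.25 (Hebp1) to -2.29 (Anxa1). Those named as higher, apart from Ttr and Plvap, were Ecrg4, Sostdc1, Cacna1e, the prostaglandin synthase Ptgs2, Sema3c, Lmntd1, the chemokine receptor Cxcr4 and Ndnf. Cxcr4 measured 5.77 and 36.9 CPM. Ttr had 0 UMIs with vehicle and 3445 CPM with rapamycin, at least 36620-fold higher against 3 counts, with 15132 UMIs in 1 cell. With doublets kept, a separate choroid plexus cluster held 7 rapamycin and 2 vehicle cells. The Plvap-led cluster, with 2 vehicle and 61 rapamycin cells, held 98.3% of these Ttr UMIs, 98.6% of those of Ecrg4 and Sostdc1 and 92.6% of those of Plvap. The UMIs of Ecrg4 came from 13 cells and those of Sostdc1 from 9 cells, out of 1469. The ratios of Ttr, Ecrg4 and Sostdc1 are therefore not read as a change across endothelial cells. In the Plvap-led cluster the level of the 6 endothelial markers was 56.7% of that of the median cluster. Without that cluster the Plvap log2 ratio went from 3.81 to 0.13. Haemoglobin transcripts, kept out of the ranking, were higher as well, with Hbb-bs at 0.0627 and 67.6 CPM.

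**Figure D3:**
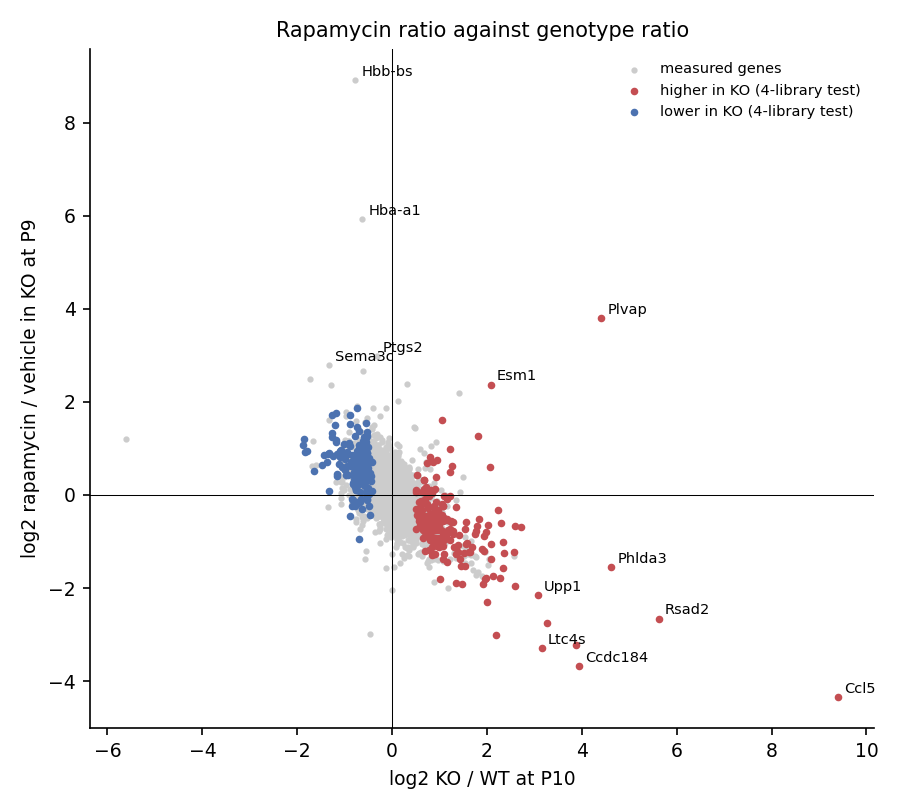
Log2 ratio of KO to WT at P10 (horizontal axis) and of rapamycin to vehicle in KO at P9 (vertical axis) in endothelial cells, 1 point per measured gene, 1 library per group, with named genes labelled. Across 5369 genes the Pearson r was -0.602, and Ccl5 lay at 9.41 and -4.34.

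By lists, the median log2 ratio of rapamycin to vehicle was -1.27 for G2 and mitosis, with 19 of 19 measured members at least 1.5-fold lower, and -1.03 for S phase. It was -0.47 for the ribosome biogenesis arm, where every one of 23 measured members was below 0, from -1.31 to -0.04. All 3 medians lay below all 10000 random lists. The amino acid arm was at -0.35 (percentile 2.68), glycolysis and hypoxia at -0.30 (2.58), sterol and lipid at -0.13 (27.5) and interferon at -0.69 (0.01). Blood-brain barrier genes were at 0.57, capillary genes at 0.75 and Notch genes at 0.82, each above all 10000 random lists. Medians of lists that were also higher in KO did not all reverse, with tip cell genes at 0.39 at P6, 0.31 at P10 and 0.61 with rapamycin, and leukocyte adhesion genes at 0.18, 0.48 and 0.34. The last median had a bootstrap interval of -0.89 to 0.64, with 2 of 10 measured members at least 1.5-fold higher and 3 lower. Ccl2, called higher in KO but under the minimum in this pair, measured 13.1 CPM with vehicle and 0.10 CPM with rapamycin. Angiogenic receptors and ligands were at 0.63 (percentile 99.99). Slco1a4, an organic anion transporter of the barrier, measured 41.7 CPM with vehicle and 215 CPM with rapamycin, and Hey1 measured 21.0 and 77.0 CPM. Immediate early genes were at 0.69 as well, opposite to the P10 pair, so the libraries also differed in that respect. Translation factors encoded by TOP mRNAs were at 0.20 (98.6), opposite to the arms above, and lysosomal genes at 0.05 (88.1). The cluster that held most cells was 0 with rapamycin and 1 with vehicle. Pdcd10 itself was 1.81-fold higher with rapamycin (interval 1.68 to 1.95).

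Genes apart in KO lay mostly the other way under rapamycin. Of the 387 genes higher in KO, 235 were measured in the P9 pair and 205 of these (87.2%) were lower with rapamycin. Of the 228 lower in KO, 168 were measured and 150 (89.3%) were higher. Among all 6181 measured genes 55.6% were lower. Across genes, which are not independent replicates, the P10 genotype ratio and the rapamycin ratio had a Pearson r of -0.602 and a Spearman rho of -0.627 over 5369 genes, with opposite signs in 73.4%. For the P6 ratio the values were -0.322 and -0.511 over 5292 genes. These 3 pairs share no library, and 3 relations were computed. Without mitotic cells the P10 relation had a Pearson r of -0.567, and the P6 relation weakened to a Pearson r of -0.272 and a Spearman rho of -0.374. Immediate early genes are among those that lie opposite, and a handling difference was not excluded as part of the relation. Pdcd10 was 1.81-fold higher with rapamycin, so fewer cells with the deletion in that library were not excluded either. The P9 libraries differ from the rest in cell barcode list, and the rapamycin pair has 1 library per arm.

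The ages were compared within each genotype. In WT, the list median of arterial genes was higher at P10 and those of cell division genes were lower. The genes highest at P10 were Ptgds, Nxpe4, elastin (Eln), matrix Gla protein (Mgp) and Cd14, with Eln at 4.59 CPM at P6 and 167 CPM at P10. The lowest were the actin regulators Cap1 and Pfn1, with Zfp69, Mest and the chemokine Ccl21a, whose reads can be shared with near-identical copies. The median log2 ratio was -1.66 for G2 and mitosis in WT and -0.47 in KO, and -1.19 and -0.66 for S phase. It was 1.24 and 0.65 for arterial genes. Interferon genes were at -0.33 in WT and -1.62 in KO. Immediate early genes were at 0.50 in WT, above all 10000 random lists, and at 0.10 in KO, so handling may add to the WT age differences. Slco1a4 was higher at P10 by 3.43 in WT and 1.73 in KO. The WT libraries also differ in sex-linked transcripts, with Xist UMIs at P6 and Y-linked UMIs at P10.

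**Figure D4:**
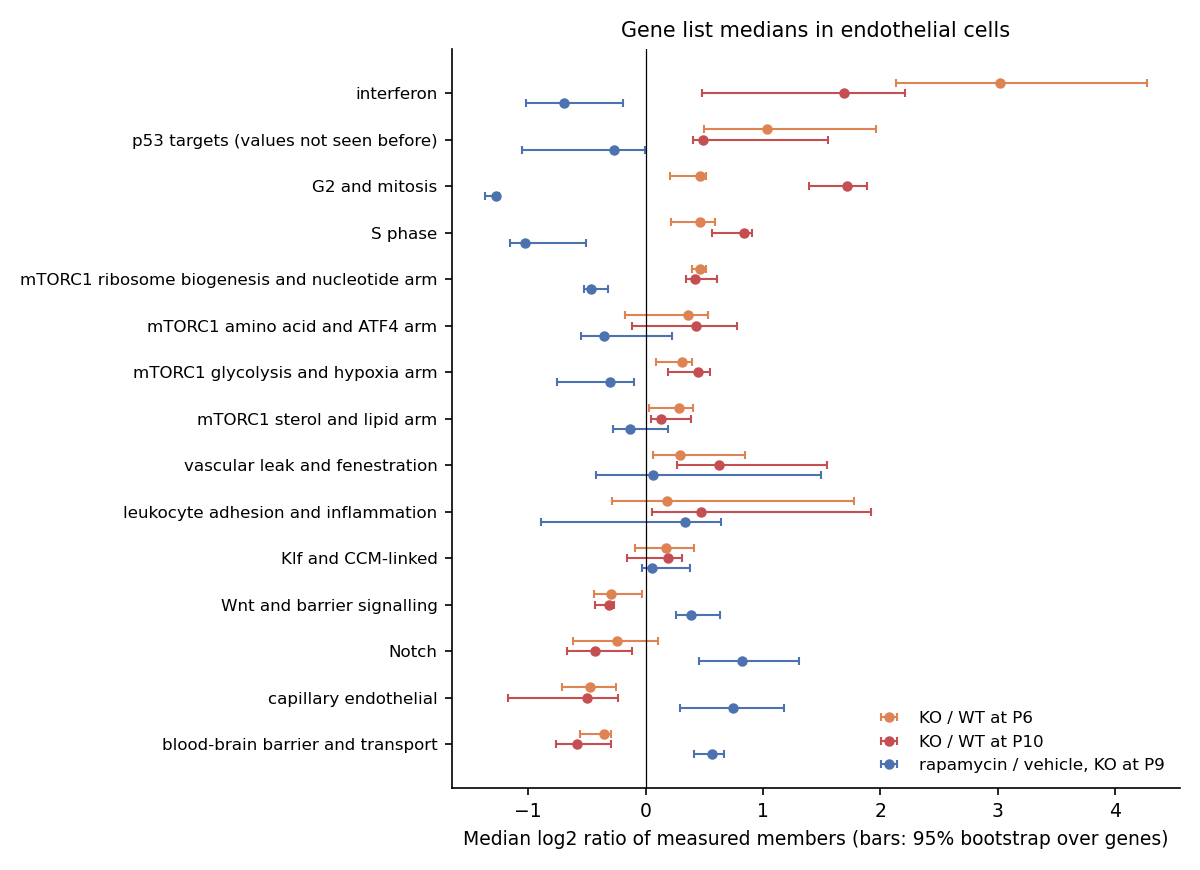
Median log2 ratio of gene lists in endothelial cells for KO against WT at P6 and at P10 and for rapamycin against vehicle in KO at P9, 1 point per list and pair, 1 library per group, with 95% bootstrap intervals over genes as bars. Interferon genes lay at 3.02, 1.69 and -0.69, and blood-brain barrier genes at -0.35, -0.58 and 0.57.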

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

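Of the tests in this part, those of chance loss of Y-linked UMIs and of a single X chromosome were chosen after the result was seen, and that of a second active X was written before.

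Sex-linked transcripts set the libraries apart. Over all kept cells, WT at P6 had 11350 Xist UMIs and 0 of 4 Y-linked genes, while 4 libraries had Y-linked UMIs, with 2906 in WT at P10, 2671 in KO at P10, 4279 with vehicle and 3225 with rapamycin. KO at P6 had 1 Xist UMI and 2 Y-linked UMIs, although the Y-linked rate of KO at P10 predicts 1204, so chance loss in a male is argued against. A second active X without Xist is argued against as well, since X-linked genes differed from autosomal genes by a median of -0.0392 (bootstrap interval -0.10 to 0.01, 170 and 5633 genes). A single X chromosome may apply, but the escape genes had a median of -0.26 (interval -0.65 to 0.14), and it cannot be told apart from other sources with so few genes. The labels give no sex, so the design offers no biological explanation, and beyond the number of X chromosomes no biological explanation was tested.

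Neuron-like cells, seen among sorted cells outside the comparisons, made up 9.89% of kept cells with vehicle and 7.78% with rapamycin, and were not found as such a cluster at P6 or P10. With the looser cell filter the shares were 13.3% and 19.3%, so their order is not read. With the stricter filter no such cluster remained apart, since the cluster then called neuron had 54 WT and 47 KO cells at P6 against 22 with vehicle and 11 with rapamycin, close to the granule neurons of the main setting (55, 54, 24 and 11). At resolution 2.0 a few were also found at P6 (28 in WT, 16 in KO) and at P10 (5 and 6).

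Of 394 listed or named genes measured at both ages, 3 were at least 1.5-fold apart in opposite directions at P6 and P10, and the difference was not tested. The placental growth factor gene Pgf had log2 ratios of KO to WT of -1.36 at P6 and 1.76 at P10. Ptgds, a prostaglandin synthase of the meninges and choroid plexus, was at 5.79 and -6.07. The haemoglobin gene Hba-a1 was at 3.45 and -0.63. The arterial list, untested too, had medians of 0.66 and -0.27, the latter turning to 0.0684 with cells weighted equally.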

How the results depend on the processing

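Alternatives on which clusters count as endothelial (mixed clusters, the Plvap-led and interferon-led clusters) and, for the genotype test, on cell filters, doublets and resolution were chosen after seeing the data. The causes of the changes below were not tested unless stated. The count of 615 genes differing between genotypes went to 1964 without a filter on low counts and 1166 with doublets kept, to 2 without the age term and to 0 on all 6 libraries with harvest day as a number and a rapamycin term (edgeR, 1044 at an unadjusted p under 0.05, where the rapamycin term also called 0, with 868). Without 1 library in turn and without the age term it ranged from 1 to 111. Leaving out 1 library leaves 1 genotype with 1 library and, without the age term, mixes genotype with age. Those counts are therefore not a check of the genotype difference alone. In 9 other fits the count stayed within 1.5 times, from 457 with DESeq2 to 854 with the stricter filter. All 20 named genes passed the threshold in the 12 fits of 4 libraries with the age term. They were picked by large ratios of the same sign at both ages in these libraries, so this is not independent support. Without the age term 2 of the 20 passed, and 0 did in that fit of all 6 libraries. Leaving out 1 library, the adjusted p of Slc25a33 ranged from 0.329 to 1, with the sign turned without WT at P10 (0.993).

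Endothelial shares moved with the definition. With the stricter filter they were 79.2% (WT P6), 87.1% (WT P10), 93.1% (KO P10), 96.1% (vehicle) and 93.1% (rapamycin), with the looser one 82.7% (vehicle) and 73.3% (rapamycin). The rule per cell gave 93.1% (WT P6), 89.9% (KO P6), 98.1% (WT P10), 97.1% (KO P10) and 90.0% (rapamycin). With mixed clusters, which add cells by construction, they were 96.2%, 94.3%, 100%, 100%, 89.5% and 91.6% from WT P6 to rapamycin. With 1 mitotic marker the ratio of dividing shares was 1.41 for KO to WT at P10 and 0.435 for rapamycin to vehicle.

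Of the list medians that stood apart from random lists, 2 turned. Without mitotic cells, the S phase list turned to -0.0744 at P6 and went to 0.30 at P10, G2 and mitosis went to 0.28 at P10 and -1.13 with rapamycin, ribosome biogenesis to 0.29 and the barrier list to -0.23 at P6, and the barrier list to 0.41 with rapamycin. With cells weighted equally, the arterial list at P10 turned to 0.0684, ribosome biogenesis at P6 was 0.36, the barrier list -0.29 and G2 and mitosis with rapamycin -1.52. The last was also -1.22 with TMM, -1.23 without mitochondrial, ribosomal and haemoglobin genes, -1.25 and -1.14 with the looser and stricter filters and -1.24 without the Plvap-led cluster. Mgp with rapamycin turned from 1.06 to -0.70 with the stricter filter and to -1.65 without the Plvap-led cluster. The relation of P6 genotype and rapamycin ratios strengthened to -0.518 at a minimum of 100 CPM. Of 1898 ratios of named genes under alternatives, 1798 moved by less than 1.5-fold and 2 turned. Scaling choices shifted the median of all genes by at most 0.06. Beyond the age term, which blocks the genotypes by harvest day, no paired analysis was possible because each group has 1 library and the labels carry no replicate numbers.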

Other observations

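The list of p53 targets was drawn up once values were known, and of the tests here, those of counting noise and of sex were chosen after the result was seen. The tests of free RNA, of deleted cells, of immune RNA and of dividing cells were written before.

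Some targets of the p53 stress response rose in KO. Among 23 targets whose values had been seen before the list was written, 13 rose in edgeR, Sesn1 fell and 9 did not pass, so this part is not independent evidence. Among 11 targets not seen, Bbc3, Ckap2 and Tap1 rose, 8 did not pass, and 8 rose adjusted over the list alone. Ccng1, a cyclin induced by p53, rose by 2.68 (SE 0.20, edgeR adjusted p = 0.00399), and Mdm2, which degrades p53, by 0.89 (SE 0.13, adjusted p = 0.0228). Bbc3, a cell death gene, rose by 1.20 (SE 0.12, adjusted p = 0.00841). Cdkn1a, the p53-induced inhibitor of the cell cycle, was at 0.29 (adjusted p = 0.371), with log2 ratios of 0.64 at P6 and 0.02 at P10. Tap1 is also induced by interferon.

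The list medians of interferon and p53 target genes were higher in KO at both ages. RNA from immune cells is argued against, since 37 immune markers summed in endothelial cells were 0.893-fold of WT at P6 and 0.914-fold at P10. More dividing cells are argued against too, since without mitotic cells the list medians kept at least 104% of their value. A sex difference at P6 may add to that pair, but at P10, where both libraries had Y-linked UMIs, with 3 and 4 Xist UMIs, the interferon median was 1.69 (bootstrap interval 0.48 to 2.21) and that of the p53 targets not seen 0.49 (0.40 to 1.55, percentile 98.8 among random lists). Both intervals lie above the bound of 0.3, so sex is argued against as the cause at P10. With the targets seen before included, the p53 median was 0.75 (0.30 to 1.79), whose lower end lies just under the bound, and the test was moved to the part not seen after this was known. An effect of the Pdcd10 deletion itself stays open as a hypothesis, with 1 library per genotype and age.

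Pdcd10 was higher with rapamycin than with vehicle, although both libraries are KO. Counting noise is argued against by the ratio of 1.81 (interval 1.68 to 1.95), and free RNA from neuron-like cells could supply 0.433% of the gap. Fewer cells with the deletion may be the cause, which would make the rapamycin pair a comparison of different recombination too. In the rapamycin library, cells without UMIs of the 10 genes named as higher in KO had 1.20-fold (1.09 to 1.33) the Pdcd10 of cells with them, but of the WT libraries, where nothing was floxed, P10 gave 1.18-fold (1.03 to 1.35) and P6 1.05-fold (0.907 to 1.23). The other KO libraries gave 1.29-fold (0.897 to 1.79) at P6, 0.973-fold (0.843 to 1.12) at P10 and 1.03-fold (0.905 to 1.17) with vehicle. The rapamycin interval overlaps those of both WT libraries, so it cannot be told apart from other sources. An effect of rapamycin on Pdcd10 transcripts was not tested.

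Arterial and coagulation genes, outside the comparisons above, changed in part with genotype. Of 13 arterial genes, Stmn2 rose, Hey1 and Gja4 fell and 10 did not pass. Of 13 coagulation genes, Anxa2 and S100a10 rose and Vwf fell, with 6 rising and 1 falling adjusted over the list alone. Anxa2 and S100a10 form a complex at the cell surface that promotes fibrinolysis. S100a10 measured 10.2 CPM in WT and 112 CPM in KO at P6, and 215 CPM with vehicle and 32.0 CPM with rapamycin.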
